A study of Mus musculus with 22 samples.

How the data were processed

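The series profiled the telencephalon of ICR mouse embryos at embryonic days 13.5 and 16.5 (E13.5 and E16.5). It lists 22 samples in 11 groups of 2 libraries, stated to be biological replicates. Native ChIP-seq of H3K9ac, H3K9cr and H3K18la and RNA-seq covered both stages, ATAC-seq covered E13.5, and 4 input libraries were listed. The inputs were not analysed here. How many embryos went into a library is not given in the sources used here.

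The authors' RNA table held expected counts, that is, estimated read counts per gene and library that were not scaled and of which 24.4% to 25.3% per library were not whole numbers, made with Salmon 1.1.0 per the submitters' processing notes. A second table deposited by the authors held log2 fold changes between the stages, and the same deposited table gave the p-value and adjusted p-value of each gene, made with DESeq2 1.26.0 per the submitters' processing notes. For ChIP-seq and ATAC-seq, 1 peak list per library was used, made with Bowtie2 2.4.1 and MACS2 2.2.7.1 on GRCm38 per the submitters' processing notes. Per the file headers, each peak had a signal value, the pileup height at its summit, whose scaling was not stated. Per the file headers, each peak also had a -log10 p-value and a -log10 q-value from the caller. Per the file headers, the last value of a peak was a ratio, the fold enrichment at its summit over the local background of the caller. Every list ended just below a q-value of 0.01. The control used for peak calling, the handling of duplicate reads and other caller settings are not given in the sources used here.

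RNA counts were rounded and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) under R 4.3.3, for E16.5 minus E13.5, with 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 16237 tested genes were called. Levels are given as CPM (counts scaled to a common library size), as mean and SD over 2 libraries. Library totals were 17059544 and 18485855 counts at E13.5 and 17533164 and 18024657 at E16.5. Where a group had 0 counts, the fold was bounded with a floor of 3 counts over its 2 libraries, and where it had up to 3 counts a 95% counting interval of the ratio was computed. Floors and intervals cover counting error only.

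The analysis plan, its alternatives and 25 gene lists were fixed before the data were examined. The lists were radial glia and neural progenitors, cell cycle, intermediate progenitors, neuronal differentiation and axon growth, deep-layer neurons, upper-layer neurons, inhibitory neurons and ventral telencephalon, Cajal-Retzius cells, synapse, astrocyte lineage, oligodendrocyte lineage, microglia, endothelial cells, pericytes, erythroid cells, embryonic globins, meninges and mesenchyme, choroid plexus, glycolysis and lactate, oxidative phosphorylation, crotonyl-CoA and acyl-CoA metabolism, histone acyltransferases, histone deacylases, histone acyl readers, and immediate early and stress genes. Cspg4 stood in the lists of both the oligodendrocyte lineage and pericytes. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over the lists. Calls of list members were also adjusted over the list alone.

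Genes were named by rule. For each list, these were up to 2 rising and 2 falling members with the largest fold change, an adjusted p under 0.05, a mean CPM of at least 1 over all 4 libraries and no overlap between the stages. To these came the 5 largest rises and the 5 largest falls under the same conditions with a mean CPM of at least 10, and 13 genes chosen in advance, of which 1 is not reported here. For each mark, the rule took the 4 rising genes with a gained peak and the 4 falling genes with a lost peak that changed most, and the stage-specific region with the highest mean fold enrichment. The text takes a selection from these, and other genes are named only where they make up a small count or were picked after their values were seen, which is then said.

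Peaks of the 4 libraries of a mark were merged where they overlapped by at least 1 bp. A region was stage-specific when both libraries of 1 stage called it and neither of the other did. With 2 libraries per stage, only 3 splits exist, so counts were set beside the other splits and no p-value was computed. Base-pair Jaccard values (shared over joint length) were computed in Python 3.11.15 and again with bedtools 2.31.1 for all 91 pairs of libraries, with a largest difference of 1e-06. Gene positions came from the NCBI RefSeq annotation of GRCm38. The plan named transcription start sites, but the table used gave no strand, so a gene counted as marked when a peak lay within 2000 bp of either of its ends. For 21887 protein-coding genes, between 30.1% and 39.4% of lower gene ends were marked by a library of the 3 marks, against 10.3% to 14.1% of the same positions moved by 50000 bp. A gene had a gained peak when both E16.5 libraries and no E13.5 library marked it, and a lost peak in the opposite case. Of these genes, 13889 were tested in RNA and used.

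The RNA change of genes with gained or lost peaks was tested with camera, and their share of rising or falling genes was set against genes marked in all 4 libraries with a two-sided Fisher exact test, adjusted over 3 marks and both directions. Marks were compared over the same genes with a two-sided exact McNemar test. Fisher and McNemar tests took genes as units, although all genes came from the same 2 libraries per group. Their p-values therefore do not measure the spread between libraries. Median log2 CPM of genes with and without a peak was compared with a two-sided permutation test of 100000 resamples in numba 0.67.0. Overlap with open chromatin was compared with 100 circular shifts of the regions along their chromosomes. Random gene sets matched for expression (10000 sets, 20 expression bins) were used in the closing tests. Further tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

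Alternatives for RNA were DESeq2 1.42.0, limma-voom, the size factors of DESeq2 or upper-quartile scaling in edgeR, other count filters, a minimum fold change, replicate number as a term, and each library left out in turn. For lists they were an estimated correlation and fry. For peaks they were windows of 1000 and 5000 bp, the stronger part of each list, the same number of peaks per library, a coverage of 50% of the region, merging over 500 bp, and each library left out. Protein-coding genes alone, gene ends judged singly, gene bodies, and genes holding stage-specific regions were added after seeing the data.

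The steps were tested on simulated data. With 50 genes changed at each size, the RNA test recovered 58% at 1.5-fold, 72% at 2-fold, 92% at 4-fold and 100% at 8-fold. Of its 181 calls, 20 were false (11.0%), above the nominal share. Far fewer genes were changed than were called in the real data, so recovery and false share may differ there. The region step recovered all 300 and 200 planted stage-specific regions among 3000 simulated ones. Each planted region was called in both libraries of its stage, so full recovery was built in. It checks the counting only and gives no sensitivity for real lists, in which replicates differ.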

Results

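The telencephalon, the part of the embryonic brain that forms the cerebral cortex and the basal ganglia, was compared between E13.5 and E16.5 in ICR mice. RNA-seq measured gene expression. Native ChIP-seq, in which chromatin is precipitated without crosslinking, mapped H3K9ac (acetylation of a histone H3 lysine), H3K9cr (crotonylation of the same lysine) and H3K18la (lactylation of another H3 lysine). ATAC-seq mapped open chromatin at E13.5. Each group held 2 libraries. RNA libraries held 17059544 and 18485855 counts at E13.5 and 17533164 and 18024657 at E16.5, with 1.60% to 1.77% from mitochondrial genes. Peak lists held 34532 and 37319 peaks for H3K9ac at E13.5 and 49652 and 50668 at E16.5. Those of H3K9cr held 28968 and 32567 at E13.5 and 41074 and 42304 at E16.5. H3K18la had 69157 and 73369 peaks at E13.5 and 62073 and 76037 at E16.5, and ATAC-seq had 26446 and 28232. Read depths behind the peak lists are unknown here. Values with ± are means and SD over n = 2 libraries.

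The RNA comparison asked which genes changed between the stages during neural differentiation, the subject of the series. Mki67 (ENSMUSG00000031004.8), a marker of dividing cells, fell from 422 ± 6.90 to 164 ± 9.09 CPM (log2 change -1.36, adjusted p = 9.5e-07). Pax6, a transcription factor of radial glia, fell from 123 ± 3.85 to 50.7 ± 4.33 CPM, and Eomes, a transcription factor of intermediate progenitors, fell from 218 ± 25.3 to 115 ± 11.4 CPM. In all, 9345 of 16237 genes (57.6%) passed the edgeR test, with 4605 higher and 4740 lower at E16.5. Changes over 2-fold were more often rises, with 2070 genes against 689. The authors' deposited DESeq2 table gave 3395 higher and 3854 lower genes, of which 3373 and 3843 were also called here in that direction.

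Among genes with a mean of at least 10 CPM over all 4 libraries, the largest rise was that of Caln1 (ENSMUSG00000060371.12), a neuronal calcium-binding protein, from 2.67 ± 0.123 to 52.3 ± 1.54 CPM (log2 change 4.29). Slco1c1, a thyroid hormone transporter of brain vessels and astrocytes, rose by 3.91 on the log2 scale, Stum by 3.73, the glial adhesion protein Hepacam by 3.62 and the GABA transporter Slc6a11 by 3.56. The deepest falls were those of the embryonic globins Hbb-y (ENSMUSG00000052187.4), from 347 ± 38.7 to 1.05 ± 0.294 CPM, and Hba-x, from 49.7 ± 11.4 to 0.526 ± 0.204 CPM. Hmga2, a chromatin protein of early neural progenitors, fell from 41.9 ± 9.10 to 1.52 ± 0.246 CPM, and Nhlh1, a transcription factor of newborn neurons, fell from 68.2 ± 7.53 to 11.0 ± 0.350 CPM. Rps2, a ribosomal protein, fell from 421 ± 64.9 to 77.6 ± 90.7 CPM (adjusted p = 0.0255), with 142 CPM in 1 E16.5 library and 13.5 CPM in the other, and its call was lost with DESeq2.

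**Figure D1:**
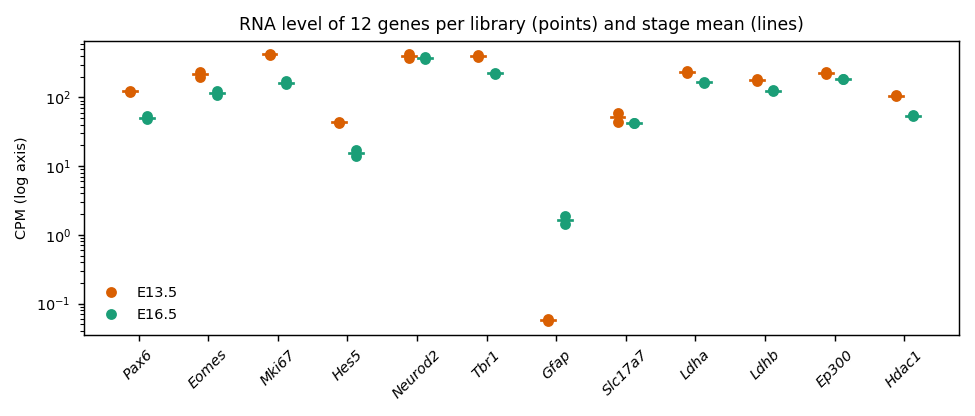
RNA level of 12 genes chosen in advance, in CPM on a log axis, with 1 point per library and a line at the mean of each stage. Mki67 lies at 422 CPM at E13.5 and 164 CPM at E16.5, and the Gfap points at E13.5 rest on 2 counts in all.

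Progenitor and division genes were lower at E16.5. All 20 cell cycle genes fell, including Ccnb1, a cyclin of mitosis, from 151 ± 4.83 to 44.98 ± 4.42 CPM and Mcm3, a subunit of the replicative helicase, from 145 ± 2.94 to 43.7 ± 3.77 CPM (camera adjusted p = 2.1e-10, and adjusted p = 0.384 with an estimated correlation). Of 16 radial glia and neural progenitor genes, 12 fell and 3 rose (adjusted p = 0.00213, and adjusted p = 0.551 with an estimated correlation). Gli3, a transcription factor of the hedgehog pathway, fell from 141 ± 1.87 to 42.7 ± 1.42 CPM, and Hes5, a target of Notch, from 43.4 ± 1.28 to 15.7 ± 2.38 CPM. The rising members were the glutamate transporter gene Slc1a3, from 107 ± 5.98 to 283 ± 26.8 CPM, the receptor phosphatase gene Ptprz1, from 494 ± 24.8 to 747 ± 39.3 CPM, and Fabp7 (log2 change 0.29), a fatty acid binding protein. Of 10 intermediate progenitor genes, 9 fell and none rose (adjusted p = 1.3e-04, and adjusted p = 0.384 with an estimated correlation). Among them the proneural gene Neurog2 fell from 176 ± 12.9 to 56.2 ± 4.81 CPM and Neurog1 from 13.1 ± 1.48 to 1.13 ± 0.137 CPM.

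Synapse and upper-layer genes were higher at E16.5. Of 24 synapse genes, 21 rose and 1 fell (adjusted p = 5.0e-07, and adjusted p = 0.395 with an estimated correlation), and the falling one, Slc17a6, lost its call under upper-quartile scaling. The kinase subunit gene Camk2b rose from 36.8 ± 0.541 to 235 ± 10.6 CPM and Grin1, a subunit of NMDA receptors, from 14.7 ± 0.235 to 89.1 ± 1.28 CPM. The vesicular glutamate transporter gene Slc17a7 stood at 51.1 ± 10.3 and 43.0 ± 0.0158 CPM (log2 change -0.25, adjusted p = 0.112). Of 10 upper-layer genes, 8 rose and none fell (adjusted p = 0.00122, and adjusted p = 0.384 with an estimated correlation). Mef2c, a transcription factor of maturing neurons, rose from 54.8 ± 0.271 to 208 ± 13.2 CPM, and Inhba, which encodes an activin subunit, from 2.39 ± 0.0221 to 18.6 ± 1.78 CPM.

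Other neuronal lists moved in both directions. Of 10 deep-layer genes, 4 rose and 5 fell, with a median log2 change of -0.12, a mean of 0.12 and a downward test (adjusted p = 0.637). Without the first or the second E13.5 library the median was -0.05 and -0.21 and the mean 0.25 and 0.02. Crym, a thyroid hormone binding protein, rose from 0.849 ± 0.498 to 7.28 ± 0.262 CPM, while Sox5 fell from 228 ± 12.5 to 110 ± 8.25 CPM and Tbr1, a transcription factor of early-born cortical neurons, from 398 ± 13.3 to 224 ± 3.78 CPM. Among 17 genes of neuronal differentiation and axon growth, 8 rose and 5 fell (adjusted p = 0.455), and upper-quartile scaling gave 9 and 4. The microtubule protein gene Mapt rose from 452 ± 8.09 to 1067 ± 61.8 CPM and Nefm, a neurofilament gene, fell from 72.2 ± 4.75 to 39.5 ± 0.930 CPM. The gene Neurod2, which encodes a transcription factor of excitatory neurons, stood at 400 ± 31.7 and 376 ± 15.8 CPM (log2 change -0.09, adjusted p = 0.237), and its change was 0.00174 under upper-quartile scaling. Of 15 genes of inhibitory neurons and the ventral telencephalon, 10 fell and 4 rose (adjusted p = 0.0357, and adjusted p = 0.551 with an estimated correlation), with 11 falling when adjusted over the list alone and 9 falling under upper-quartile scaling. The call of that list ended without the second E13.5 or the first E16.5 library (adjusted p = 0.0544 and 0.0555). Nkx2-1, a transcription factor of the ventral germinal zone, fell from 148 ± 8.40 to 36.1 ± 0.0908 CPM, while the neuropeptide gene Npy rose from 8.62 ± 1.15 to 39.0 ± 1.82 CPM. Of 8 Cajal-Retzius cell genes, 6 fell and 2 rose (adjusted p = 0.0413, and adjusted p = 0.384 with an estimated correlation), and their call ended with replicate number as a block (adjusted p = 0.0806). Ebf2 fell from 7.61 ± 1.17 to 1.24 ± 0.295 CPM.

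Glial genes were mostly higher. Of 12 measured astrocyte lineage genes, 9 rose and 3 fell (adjusted p = 0.0301, and adjusted p = 0.384 with an estimated correlation). The matrix protein gene Tnc rose from 53.3 ± 6.78 to 422 ± 48.5 CPM and the water channel gene Aqp4 from 0.892 ± 0.0132 to 7.26 ± 0.713 CPM. Gfap, an intermediate filament of astrocytes, had 2 counts at E13.5 and 60 at E16.5, a ratio of 28.8 with a 95% counting interval from 7.63 to 243. The falling members Fgfr3, Nfia and Nfib are also expressed by radial glia, and Nfia fell from 214 ± 0.173 to 110 ± 0.613 CPM. Of 8 oligodendrocyte lineage genes, 5 rose (6 when adjusted over the list alone) and 2 fell (adjusted p = 0.0413, and adjusted p = 0.551 with an estimated correlation), and upper-quartile scaling gave 6 and 1. The call of this list ended without the first or the second E13.5 library or the first E16.5 library (adjusted p = 0.0594, 0.0523 and 0.0555). Olig1 rose from 7.46 ± 0.328 to 48.2 ± 2.22 CPM, while Olig2 fell from 45.8 ± 5.08 to 29.6 ± 1.61 CPM.

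Some markers of microglia, vessels, blood, meninges and choroid plexus changed as well. All 13 microglial genes rose (adjusted p = 4.7e-05, and adjusted p = 0.384 with an estimated correlation), as did all 10 endothelial genes (adjusted p = 4.3e-05, and adjusted p = 0.384 with an estimated correlation). All 7 pericyte genes rose too (adjusted p = 2.9e-04, and adjusted p = 0.395 with an estimated correlation). Cldn5, a tight junction protein of brain vessels, rose from 13.9 ± 0.505 to 73.8 ± 0.806 CPM, and Aif1 from 0.656 ± 0.164 to 2.78 ± 0.224 CPM. Of 8 measured erythroid genes, 5 rose and 1, Slc25a37, fell (adjusted p = 0.121, and adjusted p = 0.0171 without the first E16.5 library), and that fall was not called under upper-quartile scaling. The adult globin gene Hbb-bs rose from 318 ± 61.7 to 942 ± 204 CPM. All 3 embryonic globins fell (adjusted p = 0.00273, and adjusted p = 0.384 with an estimated correlation), with Hbb-bh1 at least 36.5-fold lower. Of 8 measured genes of meninges and mesenchyme, 2 rose and 1 fell, with a median log2 change of 0.60 (adjusted p = 0.310). Without the second E13.5 library 4 rose and the median was 1.25 (adjusted p = 0.0643), and without the first the median was 0.11. Of 5 measured choroid plexus genes, Enpp2 rose and Otx2 fell, with a median log2 change of 0.14, a mean of -0.13 and a downward test (adjusted p = 0.907).

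Of 23 glycolysis and lactate genes, 6 rose and 12 fell (adjusted p = 0.235), against 8 and 10 under upper-quartile scaling. Pfkp, a phosphofructokinase, rose from 72.9 ± 1.17 to 517 ± 10.5 CPM, while the hexokinase gene Hk2 fell from 32.5 ± 0.883 to 10.2 ± 0.133 CPM. The lactate dehydrogenase genes Ldha and Ldhb fell from 235 ± 7.96 to 166 ± 3.19 CPM and from 181 ± 6.87 to 125 ± 3.93 CPM. Of 20 oxidative phosphorylation genes, 16 fell and none rose (adjusted p = 0.00162, and adjusted p = 0.384 with an estimated correlation), against 15 falling and 2 rising under upper-quartile scaling. Atp5b, an ATP synthase subunit, fell from 797 ± 7.99 to 547 ± 14.8 CPM. Of 14 crotonyl-CoA and acyl-CoA genes, 6 fell and none rose (adjusted p = 0.0683), against 6 falling and 1 rising under upper-quartile scaling. This list passed its test with no filter on low counts (adjusted p = 0.0144) and without the second E16.5 library (adjusted p = 0.0495). The dehydrogenase gene Acads fell from 16.7 ± 1.82 to 8.85 ± 0.195 CPM and Cdyl, whose product lowers crotonyl-CoA, from 12.5 ± 0.383 to 6.81 ± 0.387 CPM.

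Among 9 histone acyltransferases, 6 fell (8 when adjusted over the list alone) and none rose (adjusted p = 0.0413, and adjusted p = 0.384 with an estimated correlation), against 5 falling and 1 rising under upper-quartile scaling. Leaving out the first or the second E13.5 library or the first E16.5 library ended the call of this list (adjusted p = 0.0507, 0.0523 and 0.0555). Ep300, which can also place crotonyl and lactyl groups, fell from 226 ± 6.82 to 183 ± 0.959 CPM. Of 10 deacylases, 3 fell and 1 rose (adjusted p = 0.341), against 2 and 2 under upper-quartile scaling. Hdac1 fell from 106 ± 1.55 to 54.1 ± 1.73 CPM and Sirt7 rose from 39.6 ± 3.95 to 52.3 ± 0.453 CPM. Of 10 acyl readers, 8 fell and none rose (adjusted p = 0.0301, and adjusted p = 0.413 with an estimated correlation), 2 rose when adjusted over the list alone, and upper-quartile scaling gave 7 falling and 2 rising. Yeats4 fell from 86.6 ± 4.45 to 50.8 ± 2.81 CPM. Of 10 immediate early and stress genes, 3 rose and 4 fell, with a median log2 change of 0.12 and a downward test (adjusted p = 0.801). The chaperone gene Hspa1a rose from 0.403 ± 0.0243 to 2.90 ± 0.792 CPM and Egr1 fell from 66.3 ± 5.14 to 36.8 ± 1.12 CPM. Where no other count is given for a list, adjustment over the list alone gave the same numbers of rising and falling genes.

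Upper-quartile scaling moved the median log2 change of all genes from 0.01 to 0.10 and gave 5349 rising and 3820 falling genes. On simulated data 20 of 181 RNA calls (11.0%) were false. Far fewer genes changed there than the 9345 called in the data, so the share among real calls may differ. The setting with an estimated correlation rests on 2 residual degrees of freedom, so a call lost there decides little. It also ended the calls of lists whose estimated correlation was negative, such as microglia (-0.07) and histone acyltransferases (-0.12). Other lists that lost their call had estimates far above the preset 0.01. Among them were pericytes (0.650), radial glia and neural progenitors (0.585), synapse (0.333) and cell cycle (0.265). No list passed its test in either direction when the correlation was estimated, against 7 higher and 9 lower lists with the preset value. With fry, which asks whether the genes of a list move one way on balance and compares them with no others, the lists of crotonyl-CoA and acyl-CoA metabolism (adjusted p = 0.00848), neuronal differentiation (adjusted p = 0.00307) and deacylases (adjusted p = 0.0155) passed as well.

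**Figure D2:**
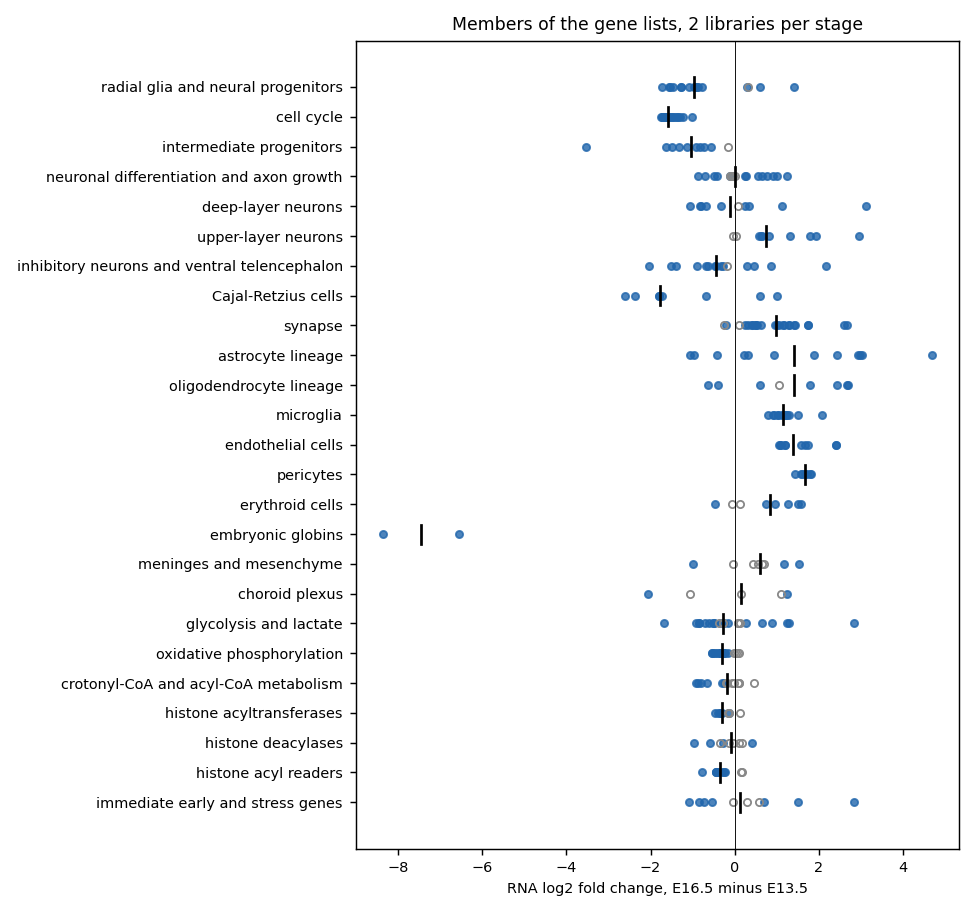
RNA log2 fold change (E16.5 minus E13.5) of each measured member of the 25 lists, with filled points for genes past the edgeR test, open points for the others and a black line at the median of the members drawn. Hbb-bh1, with 0 counts at E16.5, is left out. All 20 cell cycle genes lie below 0 and all 13 microglial genes above it.

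The peak lists were compared for regions called at only 1 stage. H3K9ac had 8603 regions only at E16.5 and 749 only at E13.5, a ratio of 11.5, and H3K9cr had 6648 and 280, a ratio of 23.7. H3K18la had 5272 regions only at E16.5 and 7208 only at E13.5, a ratio of 0.731. The splits that mixed the stages gave 802 and 815 regions for H3K9ac against 9352 for the stage split, 607 and 674 against 6928 for H3K9cr, and 2901 and 3583 against 12480 for H3K18la. Regions called in all 4 libraries numbered 27432 for H3K9ac, 24357 for H3K9cr and 33865 for H3K18la. With the same number of peaks per library, the E16.5-only and E13.5-only counts were 2692 and 2018 for H3K9ac and 1960 and 1124 for H3K9cr. The ratio of E16.5-only to E13.5-only regions depended on single libraries. For H3K9ac it was 5.02 without the first and 3.65 without the second E13.5 library, and 12.1 and 12.3 without the first or the second E16.5 library. For H3K9cr these ratios were 12.5, 4.60, 21.0 and 18.3. Without H3K18la_E16.5 replicate 1, whose peaks had a median length of 486 bp against 650 bp in replicate 2, H3K18la turned to 20987 regions only at E16.5 and 8577 only at E13.5, a ratio of 2.45. Without its first or second E13.5 library the ratio was 0.471 and 0.366, and without E16.5 replicate 2 it was 0.796.

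**Figure D3:**
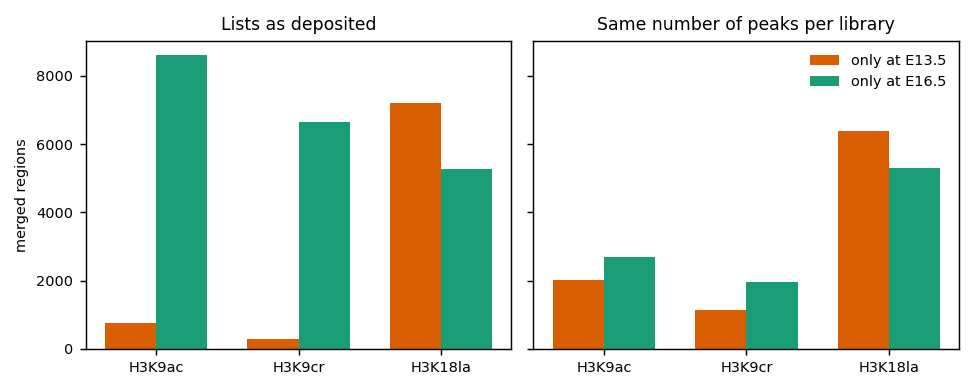
Number of merged regions called in both libraries of 1 stage and in neither of the other, for each mark, from the deposited lists and with the same number of peaks per library. For H3K9ac, the bars stand at 749 and 8603 regions on the left and at 2018 and 2692 on the right.

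The E16.5-only H3K9ac region with the highest fold enrichment lay on chromosome 1 from 58210396 to 58211208 (GRCm38) at an end of Aox4, an aldehyde oxidase gene, with 23.5 and 21.9 in its libraries. The top E16.5-only region of H3K9cr covered the same place, with 27.8 and 27.9. At E13.5, the top H3K9cr region lay on chromosome 3 from 96239504 to 96239792 near the histone genes H3c15 and H2ac19, with 55.5 and 45.6, and the top H3K9ac region on chromosome 14 from 43925238 to 43926164 near Ear10, with 33.8 and 23.4. For H3K18la, the top E16.5-only region lay in the body of Ank1 on chromosome 8 from 23100428 to 23100929, with 9.97 and 16.1. The top E13.5-only region lay between genes on chromosome 3 from 17592826 to 17593747, with 13.7 and 10.1.

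Regions called at both E13.5 libraries lay at gene ends in 45.4% for H3K9ac, 51.5% for H3K9cr and 25.1% for H3K18la, and at E16.5 in 35.7%, 40.1% and 24.9%. The share at gene ends was lower among stage-specific than among shared regions at both stages, without a test. Of the E16.5-only H3K9ac regions, 7.72% lay at gene ends, against 47.9% of those called in all 4 libraries, and 51.8% lay in gene bodies. For H3K9cr these shares were 7.18% and 53.3% at gene ends, and for H3K18la 6.58% and 30.3%. Of the E13.5-only regions, 13.6%, 21.4% and 11.9% lay at gene ends for H3K9ac, H3K9cr and H3K18la. Stage-specific regions were also narrower, with median widths of 519 and 576 bp for H3K9ac at E13.5 and E16.5, against 1586 bp in all 4 libraries. H3K9ac and H3K9cr lists overlapped nearly as much as replicates did. Their Jaccard value ranged from 0.708 to 0.764 at E13.5 and from 0.750 to 0.767 at E16.5, against 0.757 to 0.785 between replicates of these marks. H3K18la lists shared 0.346 to 0.382 with H3K9ac at E13.5, and H3K18la replicates shared 0.603 at E13.5 and 0.507 at E16.5. Across the stages, lists of the same mark shared 0.634 to 0.655 for H3K9ac and 0.631 to 0.694 for H3K9cr, below their replicates. For H3K18la the range across the stages was 0.439 to 0.504. Its E16.5 replicate 2 shared up to 0.504 with an E13.5 library, nearly as much as with its own replicate. H3K18la lists thus separated the stages less clearly than those of the other marks.

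Peaks at gene ends were set against RNA to ask whether genes that gained a mark rose. Scrg1 gained peaks of all 3 marks at E16.5 and rose from 0.113 ± 0.0745 to 3.69 ± 0.325 CPM. Ptk2b, a kinase of neurons, gained H3K9ac and H3K9cr and rose from 0.338 ± 0.224 to 5.99 ± 0.0115 CPM, and the guanine deaminase gene Gda gained H3K18la and rose from 0.401 ± 0.0571 to 11.7 ± 0.418 CPM. Gabrd, a GABA receptor subunit, gained H3K9ac and had 3 counts at E13.5 and 73 at E16.5, a ratio of 23.4 with a 95% counting interval from 7.68 to 116.

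H3K9ac was gained at 166 genes, of which 108 (65.1%) rose, against 29.0% of genes marked in all 4 libraries (odds ratio 4.57, Fisher exact adjusted p = 7.1e-21). H3K9cr was gained at 127 genes, of which 89 (70.1%) rose, against 29.0% (odds ratio 5.73, adjusted p = 7.1e-21). H3K18la was gained at 132 genes, of which 83 (62.9%) rose, against 27.4% (odds ratio 4.48, Fisher exact adjusted p = 8.5e-17). These Fisher tests ran across genes, which are not independent replicates. Median log2 changes were 1.21, 1.35 and 1.49, against -0.05, -0.05 and -0.08 for genes marked in all 4 libraries and 0.36, 0.37 and 0.46 for genes with no peak (camera adjusted p = 8.3e-12, 8.3e-12 and 2.6e-11). All 3 calls held with an estimated correlation (adjusted p = 0.0191 each). Most rising genes gained no peak, since 84.8%, 85.3% and 64.5% of the 4209 rising genes were marked in all 4 libraries for H3K9ac, H3K9cr and H3K18la. The medians for H3K9ac, H3K9cr and H3K18la were 0.66, 0.57 and 0.99 when each gene end was judged on its own and 0.28, 0.25 and 0.50 for genes holding E16.5-only regions, both chosen after seeing the data. With the stronger part of each list that for H3K18la was 0.65. For H3K18la it was 0.87 and 0.89 without the first or the second E13.5 library and 0.98 without the first E16.5 library, and these gave 240, 335 and 333 genes with a gain in place of 132. Without the first E13.5 library of their mark, 276 genes gained H3K9ac and 258 gained H3K9cr, for which the odds ratio for rising was then 3.73. The numbers of genes with a gain changed with the lists used. With the same number of peaks per library 84 genes gained H3K9ac and 67 gained H3K9cr, and with the stronger part of each list 486 and 503 did, with 265 for H3K18la.

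**Figure D4:**
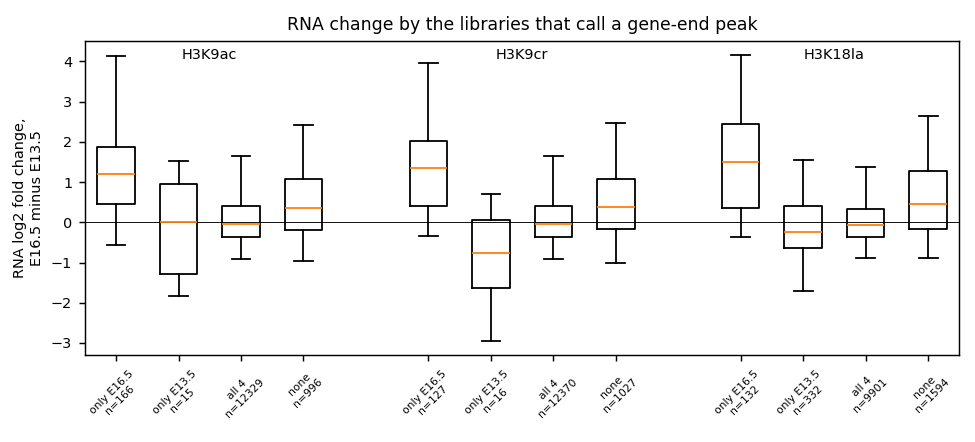
RNA log2 fold change of genes by the libraries that call a gene-end peak of each mark, with boxes for the quartiles, lines for the median and whiskers from the 5th to the 95th percentile of genes. The medians of genes with a peak only at E16.5 stand at 1.21, 1.35 and 1.49, and those of genes with peaks in all 4 libraries at -0.05, -0.05 and -0.08.

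Gains overlapped between marks. H3K9ac and H3K9cr gains shared 68 genes against 1.52 for independent lists (Fisher exact adjusted p = 7.8e-101), H3K9ac and H3K18la shared 13 against 1.58 (adjusted p = 1.2e-08), and H3K9cr and H3K18la shared 9 against 1.21 (adjusted p = 5.0e-06). With the same number of peaks per library these shared genes numbered 25, 6 and 5 (Fisher exact adjusted p = 5.6e-39, 7.3e-04 and 0.00143). The expected numbers and tests ran over all 13889 genes, but a gene marked at E13.5 cannot gain a peak. Only 1271, 1247 and 1972 genes had no E13.5 peak of H3K9ac, H3K9cr and H3K18la, so part of each overlap was built in. Overlap among the genes that could gain a peak was not tested. The control library behind each mark is unknown here, as is whether the H3K9ac and H3K9cr antibodies cross-react, so these overlaps are not independent evidence. Among listed genes, the endothelial Pecam1, Cldn5, Esam and Emcn gained H3K9ac, and none of 10 endothelial genes carried H3K18la in any library.

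Lost peaks differed between the marks. Mki67 lost H3K18la at E16.5 and kept H3K9ac and H3K9cr in all 4 libraries. Sox3, a transcription factor of neural progenitors, lost H3K18la and fell from 67.8 ± 5.47 to 14.5 ± 4.12 CPM, and Sall4, a stem cell factor, lost it and fell from 4.19 ± 1.25 to 0.414 ± 0.0317 CPM. H3K9cr was lost at Ebf2. H3K18la was lost at 332 genes, of which 144 (43.4%) fell, against 36.5% of genes marked in all 4 libraries (odds ratio 1.33, Fisher exact adjusted p = 0.0163). Their median log2 change was -0.23 (camera adjusted p = 0.0238, and adjusted p = 0.0717 with an estimated correlation). H3K9ac was lost at 15 genes (median 0.01, adjusted p = 0.997) and H3K9cr at 16 (median -0.75, adjusted p = 0.173). The H3K9cr set passed camera without the second E13.5 library of RNA (adjusted p = 0.0305) and, as chosen after seeing the data, with gene bodies (adjusted p = 0.0249) and for genes holding E13.5-only regions (adjusted p = 0.00704, but 0.0906 with an estimated correlation and 0.817 with the same number of peaks per library). Its median was 0.15 without the second E13.5 library of H3K9cr. With the same number of peaks per library, 48 genes lost H3K9ac and 45 lost H3K9cr (medians of -0.04 and -0.11). Numbers of lost genes rose when 1 library was left out. H3K18la was lost at 530 genes without its first E13.5 library and at 1001 without its second E16.5 library, H3K9cr at 42 without its second E13.5 library and at 28 without its second E16.5 library, and H3K9ac at 27 and 41 without its first or second E13.5 library and at 37 and 26 without its first or second E16.5 library. Among 4485 falling genes, 144 lost H3K18la but not H3K9ac and 4 the reverse (exact McNemar adjusted p = 6.6e-37), and 144 lost H3K18la but not H3K9cr against 7 (adjusted p = 6.8e-34). Genes are not independent replicates here either, so these p-values do not measure the spread between libraries. H3K18la was lost more often at other genes too, at 69 rising genes and at 119 genes whose RNA was not called. H3K9ac was lost at 3 and 8 of these, and H3K9cr at 2 and 7. Among 4209 rising genes, 98 gained H3K9ac but not H3K18la and 73 the reverse (exact McNemar adjusted p = 0.101). With the same number of peaks per library that last difference turned to 51 against 96 (adjusted p = 3.9e-04). Without either E13.5 library of H3K18la the median of its lost genes was -0.11 and their call ended, and the odds ratio for falling was 0.998 without the first (Fisher exact adjusted p = 1) and 1.12 without the second (adjusted p = 0.404). The Fisher call also ended with windows of 1000 bp (adjusted p = 0.0993) and 5000 bp (adjusted p = 0.0604), without the second E16.5 library of H3K18la (adjusted p = 0.0952) or of RNA (adjusted p = 0.0653) and, as chosen after seeing the data, with single gene ends (adjusted p = 0.309). For genes holding E13.5-only H3K18la regions, also chosen after seeing the data, the odds ratio for falling turned below 1, to 0.876. That is the opposite direction.

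Genes with a gene-end peak had more RNA than genes without. At E13.5 the median was higher by 3.75 on the log2 CPM scale for H3K9ac (12377 genes with and 1271 without), by 3.68 for H3K9cr and by 3.58 for H3K18la. At E16.5 the differences were 2.89, 2.93 and 2.60. Each had a permutation p of 1e-05, the smallest that 100000 resamples can give, across genes that are not independent replicates. Ldha, at 235 CPM at E13.5, had no gene-end peak of any mark in any library. Only positions near the outer ends of its annotated span were searched, so a peak at a start site further inside the gene would be missed. The absence of a gene-end peak thus does not show that the start site of Ldha was unmarked.

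Open chromatin at E13.5 lay under many marked regions. An ATAC region overlapped 44.2% of 29663 H3K9ac regions, 48.4% of 25882 H3K9cr regions and 27.7% of 50170 H3K18la regions. After circular shifts the mean shares were 1.45%, 1.41% and 1.36%, and the highest were 1.68%, 1.63% and 1.51%. Of 18286 ATAC regions, 71.8%, 68.4% and 75.1% carried H3K9ac, H3K9cr and H3K18la. Gene ends of Mki67, Hes5 and Hdac1 had a peak in both ATAC libraries, and those of Tbr1 and Ep300 in 1. Those of Pax6, Eomes and Neurod2 had none, though all 3 marks lay there in every library. The ATAC replicates had a Jaccard value of only 0.435, so a missing peak does not show closed chromatin. When a region had to be covered over 50% of its length, the shares were 3.09%, 4.32% and 3.13%, against 0.107%, 0.110% and 0.124% after shifts. ATAC regions had a median width of 389 bp, against 1328, 1296 and 1161 bp for the marked regions, so few could cover that much.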

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

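A setting with the same number of peaks per library was fixed in advance, but the tests that set it against longer peak lists, and the count of markers of other cells, were chosen only after the results were seen.

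Marks differed in the peaks lost at falling genes, and at other genes as well. H3K18la was lost at 69 rising genes and 119 genes not called, against 3 and 8 for H3K9ac. The difference is thus not particular to genes whose RNA fell. Among falling genes, those that lost H3K9ac but not H3K18la, minus those with the reverse, came to -140. The value for H3K9cr against H3K18la was -137, and both passed the exact McNemar test of the difference. The short list of H3K18la_E16.5 replicate 1 cannot be excluded. Without the first E16.5 library of both marks, 186 falling genes lost H3K18la alone and 8 lost H3K9ac alone (exact McNemar p = 3.6e-45). Leaving out a library only loosens the definition of a loss. Every gene lost in the main count stayed lost, so this test does not decide the question. Calls that come and go between any pair of libraries are excluded as the whole cause. Splits that mixed the stages gave at most 27 such falling genes against 144 in the real split, whose lower Poisson bound is 121. The stage itself, the short list and the lower fold enrichment of H3K18la peaks stay open. Median fold enrichment was 4.58 to 4.86 for H3K18la against 7.43 to 8.53 for H3K9ac, and its part was not tested.

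Genes with a gene-end peak gained at E16.5 rose more often than genes marked in all 4 libraries. Longer peak lists at E16.5 do not account for this as a whole for H3K9ac and H3K9cr, since with the same number of peaks per library the lower 95% bounds of the odds ratio were 3.23 and 3.15. For H3K18la the bound of 3.12 decides nothing, because its lists held 138110 peaks in all at E16.5 against 142526 at E13.5. Low expression of these genes does not either, since over 10000 matched sets the highest shares of rising genes were 48.8%, 50.4% and 51.5%, against 65.1%, 70.1% and 62.9% observed. More vessel, microglial, blood or meningeal cells at E16.5 cannot be told apart from a gain within neural cells for H3K9ac, because the 8 listed markers of such cells among its 166 genes are only part of what those cells express. The stage is among the open explanations and was not separated from a change in cell types.

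H3K9ac and H3K9cr regions called only at E16.5 outnumbered those called only at E13.5 by ratios of 11.5 and 23.7, and with 1 library left out by 3.65 to 12.3 and by 4.60 to 21.0. With the same number of peaks per library the ratios were 1.33 and 1.74. Equal list lengths draw such a ratio towards 1 whatever the cause, so a longer list through deeper sequencing or cleaner precipitation cannot be told apart from a true gain of marked regions. Read depths, which bear on deeper sequencing but not on cleaner precipitation, are unknown here.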

How the results depend on the processing

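The alternatives with protein-coding genes, single gene ends, gene bodies or genes holding stage-specific regions were chosen only after the results were seen, and all others were planned. Across 34 main results and 269 alternatives, 190 values kept their direction and call or stayed within 1.5 times, 51 moved, 16 reversed, 5 gained a call and 7 lost one. For 92 named genes and 1104 alternatives these numbers were 1083, 0, 1, 3 and 17, for 25 single lists and 225 alternatives 188, 0, 6, 6 and 25, and for 16 other results and 138 alternatives 95, 21, 14, 2 and 6. The cause was not tested for any change below, except where fewer libraries or shorter lists change the count by construction. With 2 libraries per stage, a stage left with 1 library was assumed to vary like the other. At least 36.5-fold is all that a count of 0 shows for Hbb-bh1.

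Replicate number as a block gave 4675 higher and 4851 lower genes. The main fit did not pair libraries by number, since the labels do not state that replicate numbers pair samples. Deviations of same-numbered libraries correlated across genes at 0.135, which does not settle whether they were paired. DESeq2 gave 3407 higher and 3894 lower genes, and leaving out libraries gave 3870 to 4099 and 4079 to 4474. A change over 2-fold left 2070 and 689. With an estimated correlation 0 lists were higher and 0 lower, which decides little with 2 residual degrees of freedom. Upper-quartile scaling turned the change of the gene Neurod2 to 0.00174. The median of the neuronal differentiation list was -0.0243 without a count filter and -0.0213 to 0.0416 with libraries left out, that of choroid plexus -0.64 to 0.93 and that of immediate early genes -0.0522 to 0.0665. The calls of Dpf3, Mbp, Slc17a6 and Slc25a37 were lost under 3 to 5 alternatives each.

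The stronger part of each list gave 118 E13.5-only and 4537 E16.5-only regions for H3K9ac, 45 and 3624 for H3K9cr, and 3904 and 2944 for H3K18la. Equal peak numbers gave 2018 and 2692 for H3K9ac and 1124 and 1960 for H3K9cr. Coverage of 50% of the region gave 1195 E13.5-only H3K9ac regions. With libraries left out, E13.5-only regions ranged from 1195 to 2758 for H3K9ac, 580 to 1589 for H3K9cr and 8577 to 19863 for H3K18la, and E16.5-only regions from 10063 to 16012, 7309 to 12156 and 7272 to 20987.

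For genes that lost H3K9ac, the median RNA change was -0.00278 with the 1000 bp window, -0.26 with the stronger peaks, -0.0428 with equal numbers, -0.0466 with single ends, -0.0237 with the replicate block, -0.15 for genes holding E13.5-only regions (also with an estimated correlation), -0.0499 for these with equal numbers, and -0.16 to 0.15 with libraries left out. Its odds ratio was 1.36, 1.04 and 1.27 with stronger peaks, single ends and genes holding regions, and 0.358 to 1.103 with libraries left out. For lost H3K9cr, the median was -0.39 with the 1000 bp window and -1.26 with gene bodies. It was -0.28 and 0.00312 for genes holding regions with all and with equal peak numbers, and -0.69 to 0.15 with libraries left out. Its odds ratio was 0.919, 0.608 and 0.876 with stronger peaks, equal numbers and genes holding regions at equal numbers, and 0.600 to 1.82 with libraries left out. For lost H3K18la, the median was -0.11 with single ends, -0.23 with an estimated correlation, -0.0250 for genes holding regions with either correlation and -0.0163 for these with equal numbers, and -0.24 to -0.11 with libraries left out. Its odds ratio was 0.876 and 0.836 for genes holding regions with all and with equal numbers, and 0.998 to 1.42 with libraries left out. The H3K9cr and H3K18la losses, which shared 0 genes, gave odds ratios of 3.79 and 7.496 with the 1000 bp window and with equal numbers.

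With the 5000 bp window, gains of H3K9ac exceeded those of H3K9cr by 24 and of H3K18la by 36 genes and passed the test. With equal numbers these gains stood at -45 for H3K9ac and -56 for H3K9cr against H3K18la, and losses of H3K9ac against H3K9cr at 2. Overlap with open chromatin was 3.09%, 4.32% and 3.13% at 50% coverage and 45.1%, 50.3% and 25.4% with stronger peaks for H3K9ac, H3K9cr and H3K18la. With libraries left out it ranged from 36.3% to 53.4%, 40.3% to 57.6% and 19.3% to 34.6%.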

Other observations

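The cell cycle test, the ribosomal protein set and the genes named in the next paragraph were chosen only after the results were seen.

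Genes of ribosomal proteins, a set without a place among the 25 lists, mostly fell. Of 91 measured, 58 fell and 5 rose, with a median log2 change of -0.20 (camera p = 4.8e-06, and p = 0.294 with an estimated correlation). Of the 332 genes that lost H3K18la, 69 rose (20.8%), against 27.4% of genes marked in all 4 libraries. Hspa1a and Hspa1b, which encode heat shock proteins, were among these 69 genes, as was Sox10, a transcription factor of oligodendrocytes, which rose from 0.694 ± 0.123 to 4.42 ± 0.546 CPM. Crym gained all 3 marks, and P2ry12, a receptor of microglia, gained H3K9ac and H3K9cr.

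Vessel markers carried little H3K18la, a pattern that was not part of the plan. Of 16 listed markers of vessels, microglia and blood with a gene-end peak of H3K9ac at E16.5, 5 also carried H3K18la. At E16.5, H3K9ac and H3K18la lay at 6 and 0 endothelial genes, 6 and 2 pericyte genes, 1 and 0 erythroid genes, and 3 and 3 microglial genes, so the count rests on vessel genes and microglial genes showed no gap. Expression-matched genes with H3K9ac carried H3K18la at a mean of 12.6 of 16, and the lowest 2.5% of the matched sets reached 9. For these 16 genes as a whole, the gap was thus larger than in genes of like RNA level in whole tissue. The test was run on the genes in which the gap was noticed, so this too stands as a hypothesis. The match was on RNA level alone. It cannot tell genes active in few cells from genes weakly active in many. No other explanation was tested.

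Cell cycle genes may lose H3K18la beyond other falling genes. Mki67, Aurkb and Plk1 lost it among 20 cell cycle genes, against 141 of 4465 other falling genes (3.16%, two-sided Fisher exact p = 0.0248, unadjusted). The test was run on the genes in which the loss was noticed, so it stands as a hypothesis.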
